A study of Mus musculus with 6 samples.

How the data were processed

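RNA was measured by bulk sequencing in 6 libraries of sorted Tregs, 3 WT and 3 KO. Per the submitters' processing notes the tools included bcl2fastq, STAR 2.4.2a and DESeq2, with the genome build GRCm38; the counting tool, its use of strand and the annotation release are not given in the sources used here. The authors deposited raw read counts per Ensembl gene, normalized counts per gene symbol and FPKM per gene symbol. The deposited normalized counts, a signal with no fixed total, equalled the raw counts divided by 1 factor per library for at least 99.87% of genes with over 50 counts, within 1e-06. The deposited FPKM values were those normalized counts divided by 1 constant per gene for 99.979% of 9335 genes checked. No column of per-sample values was left unused.

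Symbols and positions were taken by gene ID from GENCODE M21, on the same build, which matched 35412 of 37187 IDs. The unmatched 1775 IDs held 0.260% to 0.308% of the counts and stayed in the tests. Without knowledge of strand use, overlapping and antisense genes cannot be told apart.

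Raw counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, robust quasi-likelihood fit (glmQLFit in its default legacy form, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM factors. The standard error of a log2 fold change was derived from the F statistic. Gene lists, 47 written before the data were examined, of which 38 had at least 5 tested members, were tested with camera in limma 3.58.1 on voom values at an inter-gene correlation of 0.01, with the correlation estimated and fry beside it, and adjusted over the 38 lists. Principal components used the 500 most variable genes. The design, the lists, the panel and the rule for named genes were also fixed before the data were examined. Named were the panel, the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 1 CPM in a group, without predicted genes, clones, pseudogenes and antigen receptor segments, and of each list up to 4 called members with the smallest p or, where none passed, up to 2 as values; some genes under this rule are not reported here.

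Replicates were checked for duplication: within groups, chi-square over degrees of freedom between pairs of libraries ran from 5.16 to 14.7, so no pair agreed within sampling noise. The test was tried on simulated data with 200 of 13626 genes changed, in 20 draws. With gene-wise dispersions it recovered 27.3%, 67.1%, 88.5% and 97.4% of genes changed 1.25-, 1.5-, 2- and 4-fold, and 9.93% of its calls were false, above the nominal rate. With trended dispersions 4.35% of its calls were false. With no gene changed it made 3.25 calls per draw under gene-wise and 0.05 under trended dispersions. A simulated list of 30 genes changed 1.5-fold had a camera p of 3.15e-90 and one of 30 unchanged genes a p of 0.752. Simulated genes were drawn independently of each other, while estimated correlations were 0.456 for the immediate early and 0.97 for the B cell list. The simulation therefore cannot show how often camera errs on correlated lists.

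Alternatives were DESeq2 1.42.0 with default settings, limma-voom, RLE and upper-quartile factors, other filters (none, or a CPM filter of at least 1 CPM in 3 samples) and thresholds, limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(normalized count + 1), and leaving out each library. Added after seeing the data were the B cell score (mean log2 CPM of 19 markers) as a covariate (for the interferon list also with each library left out), leaving out WT replicates 1 and 3, protein-coding genes alone, edgeR's other quasi-dispersion method, and the flanking test without the Ifit family. Without WT replicates 1 and 3 a single WT library remains, which is assumed to vary like the KO libraries. Total counts of 18071928 to 21165063 set the depth, and intervals and floors of 3 counts cover counting error only.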

Results

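Messenger RNA was sequenced from regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain immune responses, sorted by CD4, CD25 and GITR from the tumour-draining lymph nodes of mice. The mice carried B16.F10 melanoma, a transplantable C57BL/6 tumour line, and nodes were taken on day 14 after 300000 tumour cells had been placed under the skin. There were 3 wild-type libraries (WT, replicates 1 to 3) and 3 from mice lacking Il33 (KO, replicates 4 to 6). Total counts ran from 18071928 in WT replicate 3 to 21165063 in WT replicate 1. The comparison asks how loss of IL-33, an alarmin cytokine read by the receptor ST2 on Tregs, changed the transcripts of these cells. The p-values measure the spread between these libraries, since the labels do not state that each came from a separate animal.

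Il33 itself was near the limit of detection in both groups. Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718 on the plus strand of GRCm38) had 7, 0 and 9 counts in WT replicates 1, 2 and 3 and 3, 8 and 2 counts in KO replicates 4, 5 and 6. The 0 counts in WT replicate 2 allow up to 0.155 CPM, for counting error only. The 16 WT and 13 KO reads did not differ in an exact binomial test of the pooled reads (two-sided p = 0.465), which compares these libraries and not the conditions. Il33 was too low to be tested and could not check the labels, because the deleted part of the gene is not given in the sources used here.

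Among the fixed panel of Treg and T helper genes, the sorted KO cells held more transcript for Ifng, Ctla4, Gata3 and Tbx21. The sort did not use Foxp3, and Ifng is also on the list of conventional and activated CD4 T cells. That list had a camera adjusted p of 0.427, and which cells held the added Ifng transcript was not tested. Ifng, the cytokine of type 1 responses, rose from 4.18 ± 0.744 to 11.2 ± 0.898 CPM (SD, n = 3 each), a log2 fold change of 1.42 (SE 0.16). Tbx21, which encodes T-bet, rose from 10.8 ± 1.70 to 15.7 ± 0.975 CPM, and the inhibitory receptor gene Ctla4 rose from 660.6 ± 74.5 to 956.7 ± 46.6 CPM. Gata3, a transcription factor of type 2 and tissue Tregs, rose by a log2 fold change of 0.31 (SE 0.07). The adjusted p-values of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000226 for Ifng, 0.00220 for Ctla4, 0.0206 for Gata3 and 0.0263 for Tbx21. Foxp3 had a log2 fold change of 0.15 (SE 0.06), with an adjusted p of 0.160 in the edgeR test. Il10 had 0.61 (SE 0.17, edgeR adjusted p = 0.0570), Tigit 0.29, Ikzf2 0.22, Il2ra 0.16, Rela 0.07, Nfkb1 -0.04, Icos -0.22, Klrg1 -0.28 and Il1rl1, which encodes ST2, -0.01 on the log2 scale, and none of these passed. Of the 14 panel genes tested, 4 passed over all genes and 7 passed when adjusted over the list alone. Gata3 and Tbx21 no longer passed without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6, with highest adjusted p-values of 0.106 and 0.115, and only Ifng of the panel passed with the B cell score as a covariate, an alternative chosen after seeing the data. Without WT replicate 2, Il10, Tigit, Ikzf2 and Il2ra also passed, at edgeR adjusted p-values of 0.00572, 0.00557, 0.0398 and 0.0294, and Tigit passed without KO replicate 4 at 0.0380.

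**Figure D1:**
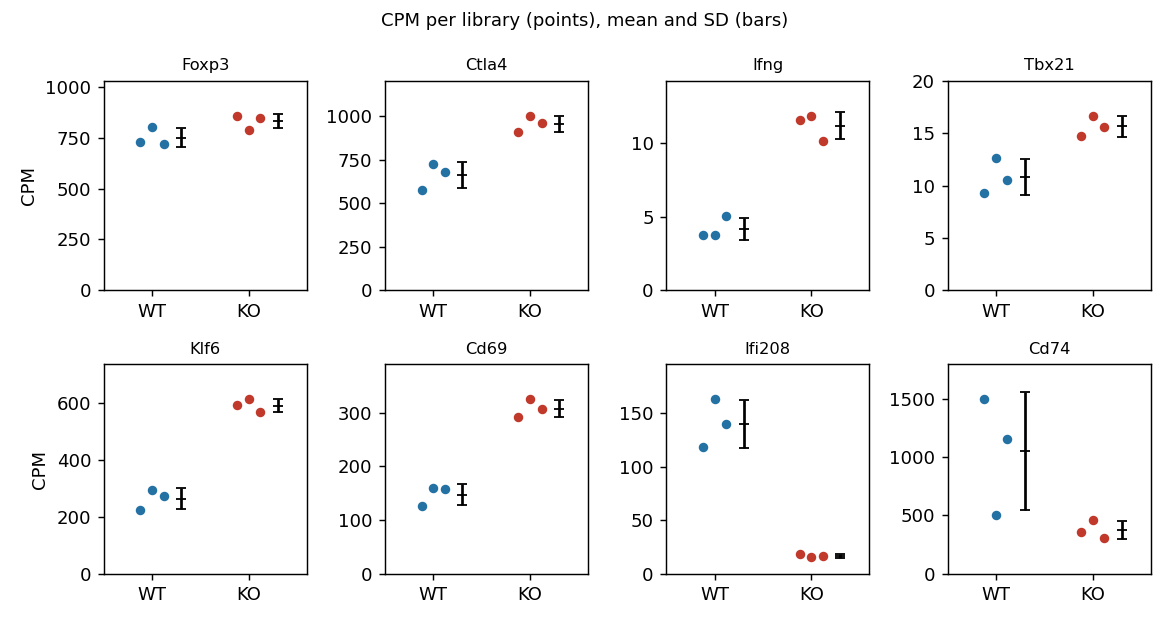
Normalised counts in CPM (y axis from 0) of 8 genes in each WT library (blue points) and KO library (red points), with the mean and SD of the 3 libraries as black bars. Ifng rose from 4.18 to 11.2 CPM, and Cd74, an abundant B cell transcript chosen after its value was seen, ran from 501.6 to 1494 CPM in WT.

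Across the transcriptome, KO Tregs differed from WT in many genes, most of them by less than 2-fold. Of 13626 genes tested, 886 passed, with 501 higher and 385 lower in KO, by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05. Changes were mostly modest, with a median absolute log2 fold change of 0.505 among the called genes and 230 of them changed at least 2-fold. Ifi208, a member of the interferon-inducible HIN-200 family, fell from 140.1 ± 22.4 to 16.7 ± 1.61 CPM (SD, n = 3 each), a log2 fold change of -3.07 (SE 0.13). This gene has close paralogs, so its count is uncertain where reads could be split between copies. Prom1 had 0 reads in WT and 70 in KO, which makes it at least 21.7-fold higher when 3 counts over the WT group are taken as the floor. Pkd1l1 had 1 read in WT and 249 in KO, a ratio of 232 with a 95% counting interval from 41.2 to 9190. The other genes of the largest rises were Nap1l3, Qrich2, Mir24-2, Tmem88, Apol8, Gucy2g, Atf3 and Mettl21c, with log2 fold changes from 2.23 to 2.65. Those of the largest falls were Cdkl1, Lamp3, Scimp, Hcrtr2, Adam23, Crispld2, Il5ra, Igf2bp3 and Stac2, from -2.61 to -2.02, and 96 further called genes of predicted, clone, pseudogene or antigen receptor type were left out of this naming. Of these falls Cdkl1, Lamp3, Hcrtr2, Adam23, Il5ra and Stac2 were lowest among WT libraries in replicate 2, where B cell marker signal was also lowest in WT. Stac2 had 8.02, 2.18 and 4.43 CPM in WT replicates 1, 2 and 3. Scimp, Crispld2 and Igf2bp3 were not lowest there. Whether RNA of other cells made any of these falls was not tested. When single libraries were left out, several lost their call. Mir24-2, Cdkl1, Lamp3, Hcrtr2, Crispld2 and Stac2 each lost it on leaving out any 1 of 4 libraries, and Atf3 and Il5ra for 1 library. The highest edgeR adjusted p was 0.0878 for Mir24-2, 0.0787 for Cdkl1, 0.0961 for Lamp3 and 0.142 for Hcrtr2, each without WT replicate 3. Without KO replicate 6 it was 0.0638 for Atf3, 0.0545 for Il5ra, 0.0698 for Crispld2 and 0.156 for Stac2. The count fell to 460 without WT replicate 1, 367 without WT replicate 3, 419 without KO replicate 5 and 408 without KO replicate 6, and rose to 1364 without WT replicate 2. It was 79 with the B cell score as a covariate, chosen after seeing the data. Under this covariate the 501 genes higher in KO kept a median of 0.885 of their log2 fold change (quartiles 0.684 and 1.11). For 334 genes lower in KO, outside the B cell, immunoglobulin and type I interferon lists, the median was 0.807 (quartiles 0.485 and 1.06). The score itself differed between the groups, which costs the test power, so the fall in calls does not measure how much of the change was lost.

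**Figure D2:**
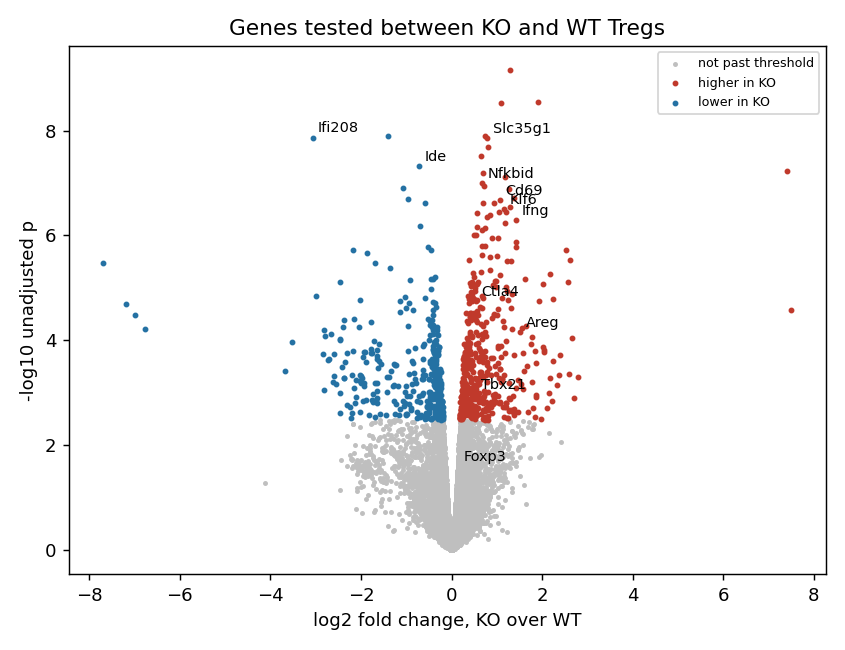
Log2 fold change of KO over WT (x axis) against -log10 of the unadjusted p (y axis) for the 13626 genes tested, with 501 genes higher in KO in red, 385 lower in blue and the rest in grey. Ifi208 stands at -3.07 and Ifng at 1.42.

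The libraries separated by group on the first principal component, which held 63.4% of the variance of the 500 most variable genes. The WT libraries lay at -26.2, -4.36 and -19 and the KO libraries at 17.1, 11.8 and 20.7. WT replicate 2 stood apart on the second component, which held 18.6%, at -21.0. Transcripts of 19 B cell markers summed to 6530, 2622 and 5244 CPM in WT replicates 1, 2 and 3 and to 1939, 2484 and 1837 CPM in KO replicates 4, 5 and 6.

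Of the 38 gene lists tested, 15 passed camera at the preset correlation. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05), and 0 passed the directional fry test (10 unadjusted). The direction of each list below therefore rests on the preset correlation and on its counts. The mixed fry test, for changes in either direction, gave adjusted p-values of 0.00322 for the immediate early list and 0.0684 for B cells. It also gave 0.000669 for the naive list, which camera did not pass, so it does not set the 15 lists apart.

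Immediate early genes, which are switched on within minutes of stimulation, were higher in KO in part. Of 32 measured members 21 rose, 0 fell and 11 did not pass, and adjusted over the list alone 24 rose and 1 fell, with a median log2 fold change of 0.728. Cd69, an early activation antigen, rose from 147.4 ± 18.99 to 307.5 ± 16.6 CPM, and Klf6, a zinc finger transcription factor, rose from 262.8 ± 36.5 to 589.9 ± 22.8 CPM (SD, n = 3 each). Rgs2 rose by a log2 fold change of 1.19 (SE 0.10) and Zfp36, which destabilises cytokine messages, by 0.50 (SE 0.06). The set test (camera, preset correlation) gave an adjusted p of 1.98e-23. It was adjusted p = 0.543 with an estimated correlation. Egr1, chosen after its value was seen, had a log2 fold change of 0.00 (SE 0.07, edgeR adjusted p = 0.998). The summed B cell marker signal was lower in KO, opposite in direction to this list. With the B cell score as a covariate 5 passed upward with a median of 0.475. The camera adjusted p at the preset correlation was then 3.75e-19. Without WT replicates 1 and 3 the median was 0.588. Both settings were chosen after seeing the data. The number risen was 12 without KO replicate 4, 12 without KO replicate 6 and 14 without WT replicate 3.

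Some genes of the NF-kB pathway and of T cell receptor activation were also higher in KO. Of 37 NF-kB genes 7 rose, 1 fell and 29 did not pass, and adjusted over the list alone 9 rose and 1 fell. Nfkbid and Nfkbia, which encode inhibitors of NF-kB, rose by log2 fold changes of 0.68 (SE 0.07) and 0.89 (SE 0.11), Nfkbiz by 0.68 (SE 0.11) and Birc2 by 0.28 (SE 0.06). Camera gave this list an adjusted p of 2.56e-05, and adjusted p = 0.543 with an estimated correlation. Nfkbiz had an edgeR adjusted p of 0.0505 without KO replicate 5 and Birc2 one of 0.0602 without WT replicate 1. Of 24 receptor activation genes 9 rose, 0 fell and 15 did not pass, and adjusted over the list alone 10 rose and 1 fell. Tnfrsf9 rose by 0.43 (SE 0.07), Cd40lg by 0.39 (SE 0.07) and Tnfrsf4 by 0.24 (SE 0.06) on the log2 scale. Cd69 was also on this list, and Tnfrsf9 was on the effector Treg list as well. Camera gave an adjusted p of 6.76e-05, and adjusted p = 0.543 with an estimated correlation. The NF-kB genes risen numbered 4 without WT replicate 3 and 3 without KO replicate 5, and the receptor activation genes 3, 4 and 5 without WT replicate 3, KO replicate 5 and KO replicate 6. Tnfrsf4 lost its call without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6, with an edgeR adjusted p of up to 0.124. The receptor activation list had a camera adjusted p of 0.0891 without WT replicates 1 and 3 and 0.550 with the B cell score as a covariate, and the NF-kB list had 4.08e-06 and 3.46e-05, with 2 genes risen under the covariate. Both settings were chosen after seeing the data, and B cell marker signal was lower in KO, opposite in direction to both lists. The NF-kB and receptor activation lists had median log2 fold changes of 0.103 and 0.126. By comparison 19 general T lineage genes had a median of 0.101 (quartiles 0.018 and 0.126). A shift of either list beyond that of the T lineage genes was not tested.

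Some Treg identity and effector genes were higher in KO, with log2 fold changes from 0.24 to 1.16 among the identity genes that passed and from 0.30 to 1.51 among the effector genes. Of 24 identity genes 8 rose, 0 fell and 16 did not pass, and 13 rose when adjusted over the list alone, with a median log2 fold change of 0.201. Nrp1, a surface receptor of thymic Tregs, rose from 205.2 ± 17.0 to 280.7 ± 11.2 CPM (SD, n = 3 each), and Entpd1 and Ikzf4 rose by log2 fold changes of 0.35 (SE 0.08) and 0.32 (SE 0.07). For this list camera gave an adjusted p of 8.85e-08, and adjusted p = 0.543 with an estimated correlation. Of 34 effector Treg genes 10 rose, 0 fell and 24 did not pass, and 13 rose when adjusted over the list alone. Penk, an opioid peptide precursor, rose from 27.4 ± 3.79 to 52.8 ± 2.93 CPM, Nfil3 by a log2 fold change of 1.31 (SE 0.13) and the chemokine receptor gene Ccr8 by 0.54 (SE 0.09). For these camera gave an adjusted p of 0.000795, and adjusted p = 0.634 with an estimated correlation. At the preset correlation the effector list no longer passed without KO replicate 5 (camera adjusted p = 0.0675). Of 16 co-inhibitory receptor genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them Pdcd1 and Cd101, with a camera adjusted p of 0.00317 and adjusted p = 0.543 with an estimated correlation. Of 20 suppressive effector genes 6 rose and 0 fell (8 and 2 adjusted over the list alone), among them Areg at 1.51 (SE 0.23) and Il1r2 at 0.71 (SE 0.12), with a camera adjusted p of 0.00988 and adjusted p = 0.543 with an estimated correlation. These lists overlap, so their counts are not independent. Ctla4 was on the identity, co-inhibitory and suppressive lists. Entpd1 was on the identity and co-inhibitory lists and Nrp1 on the identity and suppressive lists. When single libraries were left out, Entpd1, Ikzf4, Pdcd1 and Cd101 each lost their call without WT replicate 1 and without WT replicate 3, all but Entpd1 without KO replicate 4, Entpd1 and Cd101 without KO replicate 5 and all but Cd101 without KO replicate 6, with edgeR adjusted p-values of up to 0.106, 0.111 and 0.145 without WT replicate 3 and 0.1001 without WT replicate 1. The identity genes risen numbered 3 without WT replicate 1, WT replicate 3 or KO replicate 5 and 2 without KO replicate 6, the effector genes 6 without WT replicate 1 or WT replicate 3, and the co-inhibitory genes 1 without WT replicate 1 or WT replicate 3, 2 without KO replicate 5 and 3 without KO replicate 4 or KO replicate 6. Of 19 genes on the list of the IL-33 receptor and its signalling 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a camera adjusted p of 0.289. The gene that rose, Il18r1, encodes a chain of the IL-18 receptor and is also on the T-bet list. Il1rl1, which encodes ST2, had a log2 fold change of -0.01. B cell marker signal was lower in KO, opposite in direction to the genes that rose here. The effector, co-inhibitory and suppressive lists had median log2 fold changes of 0.126, 0.175 and 0.156, against 0.201 for identity genes. By comparison 19 general T lineage genes, which a lower B cell share would also raise, had a median of 0.101 (quartiles 0.018 and 0.126). A shift of these lists beyond that of the T lineage genes was not tested. With the B cell score as a covariate the identity, effector, co-inhibitory and suppressive lists gave camera adjusted p-values of 0.285, 0.574, 0.574 and 0.574, and without WT replicates 1 and 3 they gave 0.00702, 0.344, 0.262 and 0.262, both chosen after seeing the data.

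Some type I interferon response genes were lower in KO, while 5 interferon-gamma response genes were higher. Of 51 type I genes 0 rose, 12 fell and 39 did not pass, and 21 fell when adjusted over the list alone, with a median log2 fold change of -0.245. Over all genes DESeq2 called 21 of them lower and limma-voom 12. Samd9l fell from 565.4 ± 18.1 to 415.9 ± 36.9 CPM (SD, n = 3 each), Oasl1 from 16.8 ± 1.23 to 8.70 ± 1.86 CPM, Slfn1 had a log2 fold change of -0.47 (SE 0.08) and Cmpk2 of -0.62 (SE 0.13). Summed over the list, WT replicates 1, 2 and 3 held 5864, 7274 and 6403 CPM and KO replicates 4, 5 and 6 held 5744, 5769 and 5198 CPM. The median was -0.148 without WT replicate 2, and the number fallen was 19 without WT replicate 1, 3 without WT replicate 3, 7 without KO replicate 4 and 4 without KO replicate 6. With the B cell score as a covariate 2 fell with a median of -0.455 and without WT replicates 1 and 3 19 fell with a median of -0.450; the covariate median was 0.068 without WT replicate 2, all chosen after seeing the data. The type I list had a camera adjusted p of 3.29e-13, and adjusted p = 0.543 with an estimated correlation. Of 39 interferon-gamma response genes 5 rose and 0 fell (6 and 0 adjusted over the list alone). DESeq2 called 5 higher and 2 lower, and limma-voom 4 and 2. By edgeR 1 fell without WT replicate 1, WT replicate 2, KO replicate 4 or KO replicate 5. Irf1 rose by 0.53 (SE 0.06), Serpina3g by 0.41 (SE 0.08), Gbp2 by 0.32 (SE 0.07) and Cd274, which encodes PD-L1, by 0.31 (SE 0.08), with a camera adjusted p of 0.122 and adjusted p = 0.730 with an estimated correlation. Cd274 lies within 10 Mb of Il33 on chromosome 19, where called genes were over-represented. Of 26 T-bet and interferon-gamma programme genes 6 rose and 0 fell (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.0565 and adjusted p = 0.588 with an estimated correlation. Il18r1 rose by 0.42 (SE 0.07) and Nkg7 by 0.51 (SE 0.12). The interferon-gamma response genes risen numbered 3 without WT replicate 1 or KO replicate 4 and 2 without WT replicate 3 or KO replicate 5, and the T-bet genes 2 without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6. With the B cell score as a covariate 0 interferon-gamma response genes rose, with a median of -0.065 against 0.071 without it. For the T-bet list 1 rose, with a median of 0.065 against 0.022. Without WT replicates 1 and 3 the medians were -0.055 and 0.046. Both settings were chosen after seeing the data, and B cell marker signal was lower in KO. Single libraries ended the calls of Cmpk2, Gbp2, Serpina3g, Cd274 and Nkg7, with highest edgeR adjusted p-values of 0.0795, 0.0692 and 0.0518 without WT replicate 3 and 0.136 and 0.114 without WT replicate 1. At the preset correlation the interferon-gamma list passed without WT replicate 2 or KO replicate 6 (camera adjusted p = 0.00506 and 0.0162) and the T-bet list without WT replicate 2, without KO replicate 4 or with the CPM filter (0.0272, 0.0134 and 0.0231). The difference between the interferon lists was not tested.

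**Figure D3:**
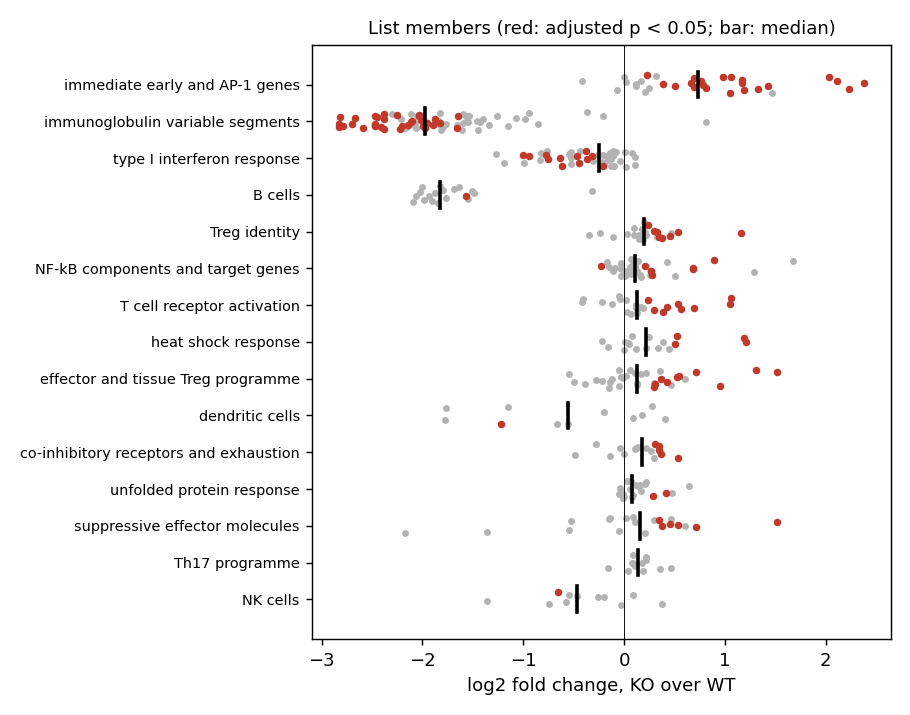
Log2 fold change of KO over WT (x axis) for each member of the 15 gene lists with a camera adjusted p under 0.05 at the preset correlation, with members past the edgeR threshold in red, others in grey and the list's median as a black bar. Immediate early genes have a median of 0.728 and type I interferon genes one of -0.245.

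Among the other programmes, some stress genes were higher, and no gene of the proliferation, oxidative phosphorylation and ribosomal lists passed. Of 17 heat shock genes 4 rose and 0 fell (7 and 1 adjusted over the list alone), and DESeq2 called 8 higher and limma-voom 4. Bag3 rose by a log2 fold change of 1.19 (SE 0.12) and Dnaja1 by 0.52 (SE 0.07), with a camera adjusted p of 0.000511 and adjusted p = 0.591 with an estimated correlation. Of 22 unfolded protein response genes 2 rose, Atf4 and Dnajb9, and 0 fell (2 and 0 adjusted over the list alone), with a camera adjusted p of 0.00476 and adjusted p = 0.591 with an estimated correlation. No gene of 12 in the Th17 list passed, over all genes or adjusted over the list alone, with Ahr at 0.46 (SE 0.14) and Il21r at 0.18 (SE 0.06), although the set test gave a camera adjusted p of 0.0402 and adjusted p = 0.543 with an estimated correlation; 4 of them had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. Of 22 naive and quiescence genes 1 rose and 4 fell (4 and 7 adjusted over the list alone), with Dapl1 at -0.81 (SE 0.15), and a camera adjusted p of 0.114. None of 44 proliferation genes, 75 oxidative phosphorylation genes or 79 ribosomal protein genes passed by edgeR, over all genes or adjusted over the list alone, with medians of 0.047, 0.011 and -0.002 on the log2 scale; at an unadjusted p under 0.05 there were 1, 7 and 2, and DESeq2 and limma-voom gave 0 for each. The direction of the proliferation list depended on KO replicates 4 and 5, with a camera adjusted p of 1.09e-07 upward without KO replicate 4 and 0.00433 downward without KO replicate 5. Camera also passed the oxidative phosphorylation and glycolysis lists without KO replicate 4 (adjusted p = 0.0321 and 0.0202), the ribosomal list without KO replicate 6 (0.00122) and the naive list without WT replicate 3 or KO replicate 4 (0.0482 and 0.0399). Of 29 glycolysis genes 3 rose and 0 fell (4 and 1 adjusted over the list alone), including Vegfa at 1.77 (SE 0.32), with a camera adjusted p of 0.179. Of 12 Th2 genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), of 13 follicular helper genes 2 rose and 0 fell (2 and 0 adjusted over the list alone) and of 23 cholesterol genes 1 rose, Insig1, and 0 fell (1 and 0 adjusted over the list alone). Their camera adjusted p-values were 0.805, 0.805 and 0.289, and the Th2 and follicular helper lists had medians of -0.04 with an upward set test. Of the follicular helper genes none rose by edgeR without WT replicate 1, WT replicate 3 or KO replicate 6, 1 rose without KO replicate 4 or KO replicate 5 and 3 fell without WT replicate 2. Of the Th2 genes 1 rose without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6, and none fell without WT replicate 3, KO replicate 4 or KO replicate 6. The unfolded protein response genes risen numbered 1 without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6. Atf4 and Dnajb9 lost their calls when single libraries were left out, with highest edgeR adjusted p-values of 0.0556 without WT replicate 3 and 0.0930 without KO replicate 6. The heat shock genes risen numbered 7 without WT replicate 2 or KO replicate 4 and 2 without KO replicate 5 or KO replicate 6, the glycolysis genes 1 without WT replicate 3 and the proliferation genes 3 without KO replicate 4, and the naive genes fallen 2 without WT replicate 1 or WT replicate 3 and 1 without KO replicate 5. No naive gene rose without WT replicate 1, WT replicate 3, KO replicate 4 or KO replicate 5. The Th17 list did not pass without WT replicate 2, KO replicate 4 or KO replicate 6 (camera adjusted p = 0.123, 0.0780 and 0.0617). The heat shock list had a camera adjusted p of 0.188 without WT replicates 1 and 3 and 0.895 with the B cell score as a covariate, the Th17 list 0.0514 and 0.0619, and the unfolded protein list 0.102 without KO replicate 5.

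Some markers of other cells also differed between the groups. Of 75 immunoglobulin variable segments 0 rose, 33 fell and 42 did not pass, and 54 fell when adjusted over the list alone, with a median log2 fold change of -1.97. The number fallen was 61 without WT replicate 2 and 11, 10, 17, 16 and 9 without WT replicates 1 and 3 and KO replicates 4, 5 and 6, each left out alone, 17 by limma-voom and 47 by DESeq2. Single segments share near-identical sequence, so their counts are uncertain. Camera gave these segments an adjusted p of 2.35e-22, and adjusted p = 0.543 with an estimated correlation. Of 19 B cell markers 0 rose, 1 fell and 18 did not pass, and 19 fell when adjusted over the list alone, with a median of -1.83. The gene that fell was Vpreb3, at -1.57 (SE 0.41). By edgeR none fell when any other single library than WT replicate 2 was left out. The number fallen was 13 without WT replicate 2, 17 by DESeq2 and 11 by limma-voom, and without WT replicates 1 and 3, left out together after seeing the data, the medians were -0.613 for the markers and -0.776 for the segments. Camera gave the markers an adjusted p of 4.91e-13, and adjusted p = 0.543 with an estimated correlation. Of 11 dendritic cell markers 1 fell, Ccl22 (5 adjusted over the list alone), and of 11 NK cell markers 1 fell, Klrk1 (3 adjusted over the list alone), with camera adjusted p-values of 0.00317 and 0.0466. For both it was adjusted p = 0.543 with an estimated correlation. Without WT replicate 2, 5 dendritic and 2 NK markers fell, and without KO replicate 5, 2 dendritic markers fell. No dendritic marker fell without WT replicate 3 or KO replicate 6, and no NK marker without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6. The NK list did not pass without WT replicate 1, WT replicate 3, KO replicate 4 or KO replicate 5 (camera adjusted p = 0.139, 0.103, 0.0931 and 0.0857), with RLE factors (0.0505) or with the CPM filter (0.0616). Vpreb3, Ccl22 and Klrk1 lost their calls when single libraries were left out, with highest edgeR adjusted p-values of 0.168 without WT replicate 1, 0.0713 without WT replicate 3 and 0.108 without KO replicate 5. With the B cell score as a covariate, chosen after seeing the data, the segment, B cell, dendritic and NK lists had camera adjusted p-values of 0.550, 0.865, 0.895 and 0.676. The score is the mean of these B cell markers, so the B cell list had to lose its difference and its value is not a result. The segments varied over the same libraries as the markers, so their value adds little. Without WT replicates 1 and 3 the dendritic and NK medians were -0.414 and -0.161, against -0.557 and -0.472 with all libraries.

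Marker lists of further cell types did not pass camera at the preset correlation. Of 13 genes of conventional CD4 T cells 3 rose, Ifng, Cd40lg and Tnfsf11, and 1 fell, Dpp4 (3 and 1 adjusted over the list alone), with a median of -0.13, an upward set test and a camera adjusted p of 0.427. Of 11 CD8 T cell genes Nkg7 rose and Klrk1 fell (1 and 2 adjusted over the list alone), of 16 macrophage genes Cd68 rose and Ly6c2 fell (1 and 2 adjusted over the list alone), and of 9 plasma cell genes Sdc1 fell (2 and 3 adjusted over the list alone), with camera adjusted p-values of 0.179, 0.471 and 0.293. Of 8 plasmacytoid dendritic cell genes Tcf4 and Siglech fell (2 and 3 adjusted over the list alone) and of 84 T cell receptor segments B230359F08Rik fell (0 and 0 adjusted over the list alone), with camera adjusted p-values of 0.194 and 0.293. That segment did not pass when any 1 of the 6 libraries was left out, with an edgeR adjusted p of up to 0.163 without KO replicate 6. None of 5 stromal genes passed edgeR over all genes (3 and 1 adjusted over the list alone; 4 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), nor any of 9 gamma-delta and NKT genes (0 and 0 adjusted over the list alone; 3 unadjusted, 1 by DESeq2 and 0 by limma-voom), with a camera adjusted p of 0.209 for both. Without WT replicate 2, 3 plasma cell genes fell and 1 rose, 2 conventional T cell genes fell and 1 gamma-delta and NKT gene fell, and without KO replicate 4, 1 plasma cell gene rose. When single libraries other than WT replicate 2 were left out no CD8 gene rose, and none fell without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 6. No conventional T cell gene fell without WT replicate 1, WT replicate 3 or KO replicate 6, no macrophage gene fell without WT replicate 1, KO replicate 4 or KO replicate 6, and of the plasmacytoid genes 1 fell without WT replicate 1 and none without WT replicate 3 or any KO library. Single libraries ended the calls of Tnfsf11, Dpp4, Cd68, Ly6c2, Tcf4 and Siglech, with edgeR adjusted p-values of up to 0.0655 without KO replicate 6, 0.0812 without WT replicate 1, 0.0558, 0.136 and 0.104 without KO replicate 6 and 0.109 without KO replicate 5.

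Genes near Il33 on chromosome 19 passed the test more often than genes elsewhere. Within 10 Mb of Il33, 15 of 81 tested genes passed, 6 higher and 9 lower in KO, against 861 of 13393 other genes, an odds ratio of 3.31 (95% interval 1.75 to 5.89, Fisher's exact test, two-sided p = 0.000198). Adjusted over the list alone, 10 rose and 11 fell. Within 20 Mb the odds ratio was 1.81 (95% interval 1.15 to 2.75, Fisher's exact test, two-sided p = 0.00719). The number lower within 10 Mb was 5 without WT replicate 1 and 3 without WT replicate 3 or KO replicate 6, and the number higher was 3 without WT replicate 3. Ide, which encodes insulin-degrading enzyme (37268743 to 37337852, minus strand), fell from 190.0 ± 14.8 to 115.4 ± 4.79 CPM (SD, n = 3 each); it lies in a segment known to vary in copy number within C57BL/6J mice, and the substrain of each group is not given in the sources used here. Slc35g1 (38395980 to 38405610, plus strand) rose from 44.4 ± 3.06 to 76.9 ± 1.70 CPM. Klf9 rose by a log2 fold change of 1.07 (SE 0.15) and Ifit1bl1 had one of -0.53 (SE 0.07). Neighbouring genes are not independent, which Fisher's exact test does not take into account.

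**Figure D4:**
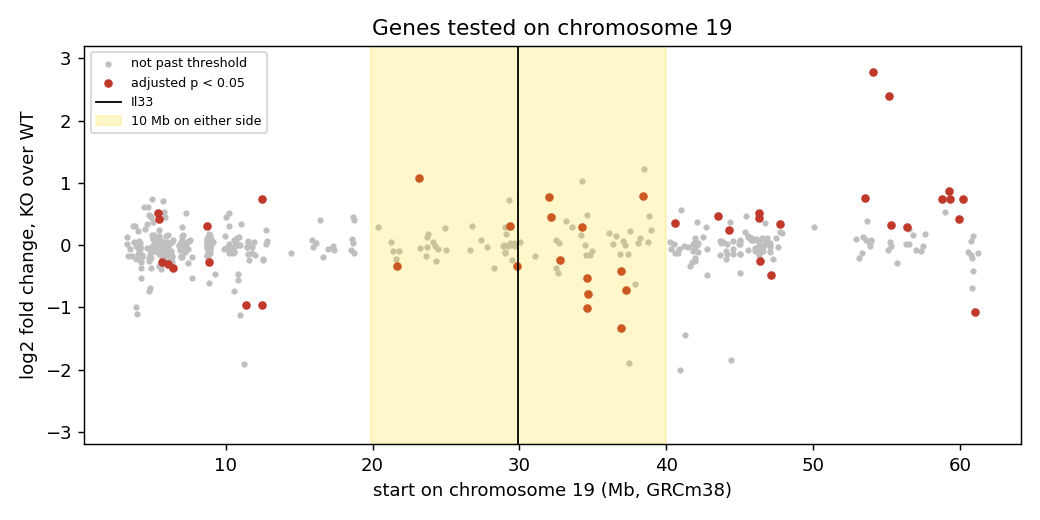
Log2 fold change of KO over WT (y axis) for each tested gene by its start on chromosome 19 in Mb (x axis), with genes past the edgeR threshold in red, others in grey, Il33 as a black line and 10 Mb on either side shaded. In the shaded window 15 of 81 genes passed.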

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

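Tests with the B cell score, without WT replicates 1 and 3, on protein-coding genes alone, with edgeR's other quasi-dispersion method and near Il33 without the Ifit family were chosen after seeing the data. The count of genes changed, 886 with 501 higher and 385 lower, stayed within 1.5 times under limma-voom, RLE and upper-quartile factors, the CPM filter, non-robust dispersion, edgeR's other quasi-dispersion method (847), the deposited normalized counts and protein-coding genes alone. DESeq2 gave 1162, with 617 lower, and 835 of the 886 were shared. With no low-count filter there were 1645, 806 higher and 839 lower; 1541 of these were among the genes tested before, and the median prior degrees of freedom moved from 9.33 to infinity. On log2(FPKM + 1) there were 142 (94 and 48) and on log2(FPKM + 0.1) 188 (123 and 65); the cause was not tested. A threshold of 0.1 gave 1412 (765 and 647) and a further 1.5-fold limit 390 (232 and 158), by construction. Leaving out single libraries gave 367 to 1364 genes changed, 239 to 626 higher and 128 to 738 lower. With the B cell score as a covariate 79 passed (51 and 28), of which 73 were shared with the 886, and without WT replicates 1 and 3 there were 282 (182 and 100), from fewer samples. Of the panel, where 4 genes passed, 8 did with no low-count filter, 1 on log2(FPKM + 1), 1 with the B cell score, 2 without WT replicates 1 and 3, and 2 to 8 when single libraries were left out. Of the gene lists, where 15 passed, 0 did with an estimated correlation, 0 by fry, 4 with the B cell score and 7 without WT replicates 1 and 3. The proliferation list, with an adjusted p of 0.718, ranged from 1.086e-07 to 0.8194 when single libraries were left out and turned downward at 0.00433 without KO replicate 5. The log2 fold change of Vpreb3 became 0.035 with the B cell score, which contains that gene and differs between the groups. The odds ratio near Il33, 3.307 within 10 Mb, was 3.622 within 5 Mb and 1.813 within 20 Mb. The first principal component held 47.33% with all tested genes and 69.8% with the CPM filter. Of 121 named genes 115 kept direction and side of the threshold under DESeq2, 109 under limma-voom, 121 with RLE factors, 111 with no low-count filter, 85 to 113 when single libraries were left out, 42 with the B cell score and 70 without WT replicates 1 and 3; on log2(FPKM + 1) 43 of 110 did. At this depth Il33 was too low to be tested. No paired analysis was possible because the groups share no replicate numbers.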

Other observations

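Chemokine receptor, survival and chromatin genes moved in part. Of 25 chemotaxis genes 3 rose and 2 fell (4 and 4 adjusted over the list alone), with Cxcr4 rising from 101.9 ± 9.47 to 198.5 ± 27.2 CPM (SD, n = 3 each) and S1pr4, a sphingosine-1-phosphate receptor gene, falling from 186.5 ± 10.1 to 141.2 ± 7.94 CPM. Of 25 survival genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; 2 rose without WT replicate 3 or KO replicate 6), with Cdkn1a at 1.12 (SE 0.17) and Pmaip1 at 0.70 (SE 0.10) on the log2 scale. Of 29 chromatin regulators 1 rose, Kdm6b at 0.67 (SE 0.10), and 3 fell (1 and 3 adjusted over the list alone), among them Kmt2d at -0.36 (SE 0.07), with an edgeR adjusted p of 0.0550 without KO replicate 6. The chromatin genes fallen numbered 5 without KO replicate 4 and 1 without WT replicate 3 or KO replicate 5, with none past the edgeR threshold without KO replicate 6, and the chemotaxis genes 1 without WT replicate 1 or WT replicate 3. Camera adjusted p-values of these lists were 0.289, 0.293 and 0.453. With the B cell score as a covariate, chosen after seeing the data, 1 chemotaxis gene rose and 0 fell. No survival or chromatin gene passed with it. The chemotaxis, survival and chromatin medians were then -0.145, -0.036 and -0.047, against -0.066, 0.010 and 0.000 without it. Nnt, chosen after its value was seen, rose from 33.5 ± 2.03 to 54.0 ± 2.54 CPM. Nnt is known to carry a deletion in C57BL/6J mice and not in C57BL/6N, and whether the groups differ in substrain, which would bear on calls outside the Il33 window too, was not tested.

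The tests on B cell transcripts, on the B cell share and on immediate early genes were chosen after the results were seen, and those on sample splits and on genes near Il33 before. The 10 splits of the 6 samples are too few for a share under 0.05. The real split gave 886 genes by edgeR and 1 split of 10 reached that number, and the highest of the other splits gave 0, with up to 829 genes at an unadjusted p under 0.05 and 0 by limma-voom.

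Called genes were over-represented near Il33, with an odds ratio of 3.307 within 10 Mb, so variants carried with the targeted allele may account for part of the 15 calls there. With the Ifit family and receptor segments left out, chosen after seeing the data, the ratio was 2.86 (Fisher's exact test, p = 0.00239). Fgfbp3 and Btaf1, the called genes nearest to Ide, also fell, with log2 fold changes of -1.34 and -0.41. They and Ide were kept in that test. Whether the groups differed in copy number in the segment that holds Ide was not tested. Variants carried with the targeted allele would leave the 861 calls elsewhere open, and an effect of Il33 loss on its neighbours was not tested.

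The B cell list was lower in KO by camera at the preset correlation, though with an adjusted p of 0.543 with an estimated correlation and 1 of 19 markers past the edgeR threshold, and its values differed most between WT libraries, with Cd74 (edgeR adjusted p = 0.187) at 1494, 501.6 and 1153 CPM in WT replicates 1, 2 and 3 and 358.9, 458.2 and 306.7 CPM in KO replicates 4, 5 and 6. RNA of B cells is a candidate source, although the sort on CD4 should remove them: for the median of 19 markers the SD of the log2 ratio to the others was 0.141 of the SD of their mean. Ighm, the most abundant marker, was an exception, at 1270 ± 195.3 CPM in WT and 1019 ± 97.0 CPM in KO (SD, n = 3 each), while Cd74, the next, had 1050 ± 504.2 and 374.6 ± 77.0 CPM. With the B cell score as a covariate the type I interferon list had a median of -0.455 (quartiles -0.784 and -0.332) against -0.245 without it, but 0.068 when WT replicate 2 was left out as well, the only WT library close to KO in B cell signal. For 334 other genes lower in KO a median of 0.807 of the log2 fold change was left, with quartiles of 0.485 and 1.06, so for both a higher B cell share in WT cannot be told apart from the genotype.

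Immediate early genes were higher in KO by a median log2 fold change of 0.728. A lower B cell share would raise T lineage genes as much. The 19 T lineage genes had a median of 0.101 (quartiles 0.018 and 0.126), and from 0.036 to 0.13 when single libraries were left out. This argues against dilution as the whole cause. Even so, with the B cell score as a covariate the immediate early median was 0.475 and 5 of these genes passed against 21. The score itself differed between the groups, which costs that test power. Without WT replicates 1 and 3, the libraries with the most B cell signal, the immediate early median was 0.588. Stress during tissue preparation may also raise these genes, and the heat shock list, with a fry directional p of 0.104, left this open. A response of the cells to the loss of Il33 stays open as well and cannot be told apart from preparation, since no label gives the order or day of handling.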
